A study of Danio rerio with 15 samples.

How the data were processed

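RNA from whole zebrafish embryos at 5 days post fertilization was hybridised to 15 two-channel Agilent arrays. Per the labels, embryos were held at 100 nM retinoic acid (RA) or 100 nM 9-cis retinoic acid (9cRA), for 24 h from day 4 or for 72 h from day 2. The labels do not state which isomer the compound named retinoic acid was; 9-cis retinoic acid is a geometric isomer of the all-trans form. Each of the 4 groups had 3 biological replicates of 50 embryos, and 9cRA 72 h replicate 2 was hybridised on 2 arrays, which were averaged and counted as 1 replicate. On these arrays the treated RNA was in Cy5 and a pooled control was in Cy3, per the labels. The control is named both as a 0.1% DMSO pool and as a water control in the labels and is called the control pool here. The labels do not say whether 1 pool served both exposure times. The remaining 2 arrays carried 9cRA RNA in both channels (self-to-self arrays), and the labels give no exposure time for them.

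Total RNA was labelled from 200 ng with a low-input amplification kit, per the labels. Images were quantified by the authors with Agilent Feature Extraction 10.5.1.1, per the file headers. The spot intensity columns hold median signals and local backgrounds on a linear scale, not yet normalized, per the file headers. The log ratio column of the deposited files is log10 of red over green after the software's own background subtraction and dye normalization, per the file headers. The authors' series table was used only as an alternative. Set against the scanner values, its columns matched log2 of Cy5 over Cy3, with a slope of 0.98 to 1.01 over spots brighter than 2000 units and a correlation of at least 0.99895 with the ratios computed here, so its scale and direction were taken from that match. Its column medians lay between -0.0051 and 0.0060, so the deposited log2 values are centred near 0. The normalization behind them is not given in the sources used here.

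Every array held 45220 spots, of which 1417 were controls and 43803 were not. Background was corrected with normexp (offset 50) and the log2 ratio of Cy5 over Cy3 was normalized within each array by loess, in limma 3.58.1 under R 4.3.3 with version 1.17.8 of data.table and version 2.0.0 of jsonlite. The files carry median and not mean signals, so median signals replaced the mean signals planned before the data were examined. Spots marked non-uniform, 1 to 76 per array, were removed before the background fit, a step chosen after the data were seen, and a fit with these spots kept is given as an alternative. With the other outlier spots, 10 to 78 spots per array were left out. Control spots carried no weight in the loess fit and were left out afterwards. Spots of 1 probe were averaged. Accessions on the array were matched without version numbers to a RefSeq gene table of assembly GRCz12tu, used for names only. This named 25069 of 43603 probes, and the other 18534 kept the identifier of the array design, giving 28550 distinct genes and identifiers. A gene was represented by its brightest probe, and a disagreement among the probes of a named gene is stated where it occurs. Tested were 22282 genes and identifiers well above background in either channel on at least 3 of the 12 treated replicates, 11760 of them with a gene name and 10522 with an identifier alone; both are called genes below. The array design was annotated on danRer6 (Zv8), and no coordinates are given.

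Group means were tested against 0 with limma (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjustment, called at an adjusted p under 0.05) in 1 fit of the 12 replicates. RA minus 9cRA at each time, 72 h minus 24 h within each compound, and the compound by time interaction were contrasts of that fit. The control pool counts as 1 control sample, so a test against it leaves out the control's own spread, and without dye swaps a dye effect does not cancel in it. A dye effect common to all arrays does cancel in the contrasts between compounds and times. Adjusted p values below come from limma and, for lists, from its camera test with an inter-gene correlation of 0.01 over 32 fixed lists. With a correlation estimated from the data, 0 of the 92 list calls held, and that adjusted p is printed with the calls. Replicate numbers were tested as pairs on the values, since the labels do not say what a number shares. Deviations from group means correlated at 0.367, 0.608 and 0.270 between RA 24 h and RA 72 h replicates of the same number, all over 0.1, so the value with a replicate block is given for time in RA. In each other comparison of groups at least 1 of the 3 correlations was under 0.1. The number of replicates limits the precision of every array value, and errors after ± are SDs over 3 replicates for a group and standard errors for a difference.

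The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Named against control were each measured member of the list of retinoic acid turnover and storage genes, and the 10 largest positive and 10 largest negative called genes with a symbol. These had to have 1 sign in all 3 replicates and to keep that sign and at least 0.5 of their size after the mean of the self-to-self arrays was subtracted. Between compounds or times the 10 largest called genes each way with non-overlapping groups qualified, and in each described list up to 4 called members with the largest log2 ratios. None of the named genes was below background or saturated throughout a group.

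Alternatives were no background correction, Agilent's log ratio, median centring in place of loess, no filter and a stricter filter, every probe on its own, either array of 9cRA 72 h replicate 2 alone, the replicate number or the slide as a block, only the groups compared, eBayes with trend and robust, a fold of at least 1.5, the authors' series table, subtraction of the self-to-self mean, and each replicate left out. Leaving out the slide scanned on the other day, keeping all spots in the background fit, time comparisons within 1 slide, and the list tests with slide as a block, all spots or a replicate left out were added after the data were seen. Tests on simulated data without a dye effect had 200 of 22105 genes changed. For RA 72 h against control, 61.2%, 95.5% and 100% of genes changed by log2 0.5, 1 and 2 were called, with 10 unchanged genes. For RA minus 9cRA at 72 h the shares were 29.9%, 83.6% and 98.5%, with 15 unchanged genes, and for RA 24 h without any change 0 genes were called. In RA 72 h the 1 list shifted by 0.5 was called, and 0 unshifted ones.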

Results

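Gene expression was measured in whole 5-day zebrafish embryos after 24 h or 72 h of 100 nM RA or 9cRA. Each of the 4 groups had 3 replicates of 50 embryos. The study asked what each retinoid changed at each exposure time against a pooled control on the same array. Median signals per array ran from 138 to 241 units in the treated channel and from 96.5 to 174 units in the control channel, over backgrounds of 50 to 53 and 26 to 37.5 units. Between 60.1% and 78.7% of spots were well above background in the treated channel and between 57.3% and 83.6% in the control channel, and 0 spots were saturated. Arrays of 1 group correlated at r of 0.238 to 0.849 in log2 ratio across genes (median 0.656, 15 pairs). The 2 arrays of 9cRA 72 h replicate 2 were at 0.599, other pairs of that group at 0.346 to 0.847. Between groups r was -0.404 to 0.817 (median 0.341, 63 pairs), lowest for 9cRA 72 h replicate 1 with RA 72 h replicate 2. The labels give the dyes of every array, so the direction of the ratios was kept. Genes are not independent replicates in these correlations.

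The arrays lay on 4 slides scanned on 2 days. The slide scanned on the first day held 9cRA 72 h replicate 1, the first array of 9cRA 72 h replicate 2 and a self-to-self array. A second slide held the 3 replicates of 9cRA 24 h and 9cRA 72 h replicate 3, and another held RA 24 h replicate 1 and the 3 replicates of RA 72 h. The last held RA 24 h replicates 2 and 3, the second array of 9cRA 72 h replicate 2 and the other self-to-self array. No slide held both compounds at the same exposure time.

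RA for 24 h raised the genes that clear and store retinoic acid in the embryos. The cytochrome P450 genes cyp26c1, cyp26a1 and cyp26b1, whose enzymes oxidise retinoic acid, rose by log2 ratios of 1.92 ± 0.27, 1.90 ± 0.54 and 1.42 ± 0.50 (SD, n = 3). The retinaldehyde reductase gene dhrs3a rose by 1.29 ± 0.40 and dhrs3b by 0.81, and the retinol-esterifying genes lratb.2 and lrata rose by 0.95 and 0.35. The retinol dehydrogenase genes rdh12 and rdh8a were each at 0.29, and at 0.03 and 0.10 after self-to-self subtraction (adjusted p = 0.942 and 0.635). The largest rise was that of fkbp5, a co-chaperone of the glucocorticoid receptor, at 2.15 ± 0.19 (adjusted p = 2.58e-06, higher in 3 of 3 replicates). Also raised were the muscle ubiquitin ligase gene fbxo32 (1.89 ± 0.48), the insulin-like growth factor binding protein gene igfbp1b (1.85 ± 0.68), the ammonia transporter gene rhcga (1.77 ± 0.11), leg1.1, diabloa, itih3a.1 and ces2a. Among the falls were nucks1a (-1.44 ± 0.34), the fin fold actinodin gene and4 (-1.43 ± 0.47), the cartilage collagen gene col2a1a (-1.43 ± 0.61) and the nucleoside transporter gene slc29a1a (-1.35). The growth factor gene ptn was at -1.27, and for it 1 of the 2 other probes had the same sign. The falls of nudt21, rn7sk, magoh, cebpz and ntmt2 lay between -1.24 and -1.21.

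All 9 measured genes of retinoic acid turnover and storage were called higher in the fit with the dye effect left in, and 9 adjusted over the list alone (adjusted p = 2.36e-08, and 0.298 with an estimated correlation). Lens crystallins, the structural proteins of the lens, had 31 of 50 members higher and 0 lower, with crygm1 at 0.95 and cryaa at 0.87. Adjusted over the list alone 33 were higher and 2 lower (adjusted p = 1.73e-12, and 0.298 with an estimated correlation). Liver plasma proteins had 17 of 37 members higher, led by itih3a.1 (1.5), the urate oxidase gene uox (1.33) and ambp (1.32). A total of 18 were higher adjusted over the list alone (adjusted p = 2.87e-07, and 0.816 with an estimated correlation). Of 26 exocrine pancreas genes, 6 rose, among them cela1.1 (1.44), cela1.6 (1.18) and prss1 (1.15), and 8 rose adjusted over the list alone (adjusted p = 0.000299, and 0.816 with an estimated correlation). Ribosomal proteins had 32 of 73 members higher (rpsa 0.76, rpl8 0.69) and 34 adjusted over the list alone (adjusted p = 3.78e-07, 0.525 with an estimated correlation and 0.558 after self-to-self subtraction). Innate immunity genes had 11 of 34 members higher and 1 lower, with cfd at 0.94, socs3a at 0.86 and isg15 at 0.65. Of the 34, 12 were higher and 2 lower adjusted over the list alone (adjusted p = 0.00195, and 0.596 with an estimated correlation). Heart muscle genes had 3 of 18 members higher (myh7l 0.73, myh7 0.43, and actc1a 0.22, which was -0.03 with Agilent's log ratio; 3 of 5 and 1 of 3 other probes of myh7l and actc1a had the same sign) and 1 adjusted over the list alone. Endocrine hormones had 3 of 17 higher (pth1b 0.49) and 1 lower (pcsk2 -0.44), with 4 and 1 adjusted over the list alone. The adjusted p was 0.0331 for both, and 0.816 and 0.298 with an estimated correlation.

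Cartilage and bone genes were lower in 14 of 36 members and higher in 2, with col2a1a, col9a1b (-0.93), col11a2 (-0.80) and matn4 (-0.70) lowest. Adjusted over the list alone 14 were lower and 4 higher (adjusted p = 0.00685, and 0.298 with an estimated correlation). Their median of -0.28 became 0.06 under median centring, where the median of all genes stood at 0.11. Cell cycle genes were lower in 6 of 39 members, among them mcm2 (-0.50), uhrf1 (-0.49) and ccnb1 (-0.42, with 3 of 5 other probes of the same sign), and 3 were lower adjusted over the list alone (adjusted p = 2.37e-05, and 0.816 with an estimated correlation). Over alternatives the adjusted p of the 10 lists ran from 3.99e-30 to 0.816.

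With limma, 5575 of 22282 genes changed at 24 h of RA, 2811 higher and 2764 lower, and 75 rose and 73 fell at least 2-fold. Of the calls 50.4% were higher, and 75% were with median centring in place of loess, where the median of all genes stood at 0.112 against 0.004 with loess. After self-to-self subtraction 62 genes were called, 42 higher and 20 lower, and with slide as a block 32 were. Without RA 24 h replicate 1, 2 or 3 the count was 1180, 1866 or 3630. The rises of fkbp5, cyp26c1, cyp26a1 and dhrs3a were called in all 29 alternatives, with highest adjusted p of 0.0108, 0.00498, 0.03 and 0.0403. The rise of igfbp1b lost its call after self-to-self subtraction (1.67, adjusted p = 0.197) and with slide as a block (1.99, 0.142), within a range of 0.000782 to 0.197. The heart muscle list lost its call without RA 24 h replicate 1 (adjusted p = 0.106) and with slide as a block (0.108), and the endocrine hormones list without replicate 3 (0.0667) and with slide as a block (0.0962). Median centring ended the calls of heart muscle (0.0808), endocrine hormones (0.144), cartilage and bone (0.144), cell cycle (0.157) and innate immunity (0.0549).

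**Figure D1:**
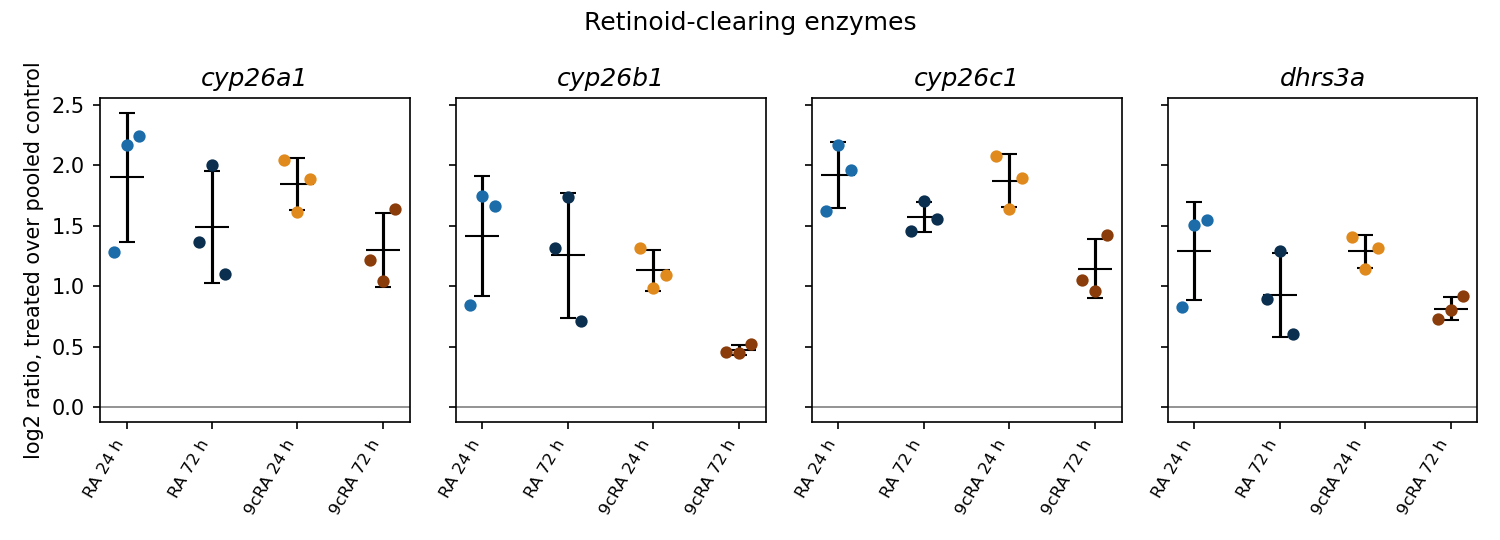
Log2 ratio of treated embryos over the control pool (y axis) for the retinoid-clearing enzyme genes cyp26a1, cyp26b1, cyp26c1 and dhrs3a in the 4 groups; dots are replicates, bars the mean of 3 and whiskers the SD.

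After 72 h of RA the same enzymes stood above control. The log2 ratio was 1.58 ± 0.12 for cyp26c1, 1.49 ± 0.46 for cyp26a1, 1.26 ± 0.52 for cyp26b1 and 0.93 ± 0.35 for dhrs3a (SD, n = 3). Also raised were lratb.2 (0.80), dhrs3b (0.61), rdh12 (0.38, and 0.11 after self-to-self subtraction) and lrata (0.31), while rdh8a at -0.13 was not called (adjusted p = 0.0653, the other probe of opposite sign, and 0.57 under median centring). The largest rises were those of fkbp5 (2.27 ± 0.19), whose other probe had the opposite sign, and igfbp1b (2.09 ± 0.78). The glycolytic regulator gene pfkfb4b rose by 1.48 ± 0.25, the pyruvate dehydrogenase kinase gene pdk2b by 1.39 ± 0.58 and the arginase gene arg2 by 1.36. The ratios of ggact.1 (1.59), rhcga (1.56 ± 0.62) and diabloa (1.47) were of similar size. The falls were larger than the rises, led by the small nuclear RNA gene rn7sk, whose product restrains transcript elongation, at -2.58 ± 0.31 (adjusted p = 0.000164), by ptn at -2.56 ± 0.46 and by nucks1a at -2.18 ± 0.42. The lens crystallin gene crygm2d6 (-2.06 ± 0.07), the phosphatase gene ptenb (-1.84 ± 0.51) and and4 (-1.84 ± 0.91) fell as well. So did tmem208 (-1.96), nyap2a (-1.92), ubap2a (-1.89) and the basement membrane collagen gene col4a5 (-2.16, the other probe of opposite sign).

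Turnover and storage genes were higher in 8 of 9 members, and in 8 adjusted over the list alone with rdh8a lower (adjusted p = 0.00207, and 0.91 with an estimated correlation). The anterior and central hox genes, which pattern the hindbrain and trunk and respond to retinoic acid, had 15 of 24 members higher and 5 lower, and 18 and 5 adjusted over the list alone. Of these hoxb5b rose by 0.82, hoxb8b by 0.73 and hoxb5a by 0.65, and hoxc6a, whose other probe had the opposite sign, was at -0.63 (adjusted p = 0.0221, and 0.91 with an estimated correlation). Liver plasma proteins were higher in 7 of 37 members, among them plg (1.02), agxta (1.01) and apoeb (0.83, and -0.18 with slide as a block). A total of 5 were higher adjusted over the list alone (adjusted p = 0.0221, and 0.91 with an estimated correlation). Cell cycle genes were lower in 14 of 39 members, with mcm6 at -0.61, ube2c at -0.53 and aurkb at -0.53. Under median centring the list stood at 0.28, as all genes did. The count adjusted over the list alone was also 14 (adjusted p = 0.0168, and 0.91 with an estimated correlation). Over their alternatives the adjusted p of the 4 lists ran from 3.01e-08 to 0.91. Exocrine pancreas genes had 1 of 26 members higher, and their medians were 0.14, 0.70 and -1.21 in RA 72 h replicates 1 to 3. In replicate 3 the liver and intestine medians were -0.19 and -0.65. Across genes r of that array with 9cRA 72 h was 0.157 (replicate 1), 0.341 and 0.702 (arrays of replicate 2) and 0.633 (replicate 3). With RA 72 h replicates 1 and 2 it was 0.613 and 0.423. Its fkbp5 value, 2.42, stood with the other RA 72 h replicates (2.06 and 2.34) and over 9cRA 72 h (0.61 to 0.84).

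With limma, 9845 genes changed at 72 h of RA, 4686 higher and 5159 lower, and 90 rose and 453 fell at least 2-fold. Of the calls 47.6% were higher, and 71.4% of 15518 calls were with median centring, where all genes had a median of 0.28 against 0.008. Subtracting the self-to-self mean left 1808 calls, 690 higher and 1118 lower, and with slide as a block limma called 0. A fit of RA 72 h alone called 3866. The call of lrata was lost in 17 of 28 alternatives. With the slide block cyp26c1 stood at 2.11 (adjusted p = 0.0604; range 2.2e-06 to 0.0604), fkbp5 at 2.13 (0.143; from 2.46e-07) and rn7sk at -1.85 (0.251; from 5.86e-06), while pdk2b fell to 0.47 and arg2 to 0.57 (0.653 and 0.593). The first 3 genes kept their calls in the 28 other alternatives. A single array of RA 24 h ties the slide of all 3 RA 72 h replicates to the others. Without RA 72 h replicate 1 the count was 5564. The hox list lost its call without replicate 3 (adjusted p = 0.0704), with slide as a block (0.121) and after self-to-self subtraction (0.065), the range for the anterior and central hox genes being 0.0028 to 0.91. The call of liver plasma proteins ended without replicate 1 (0.412) or 2 (0.0881) and with slide as a block (0.402). That of cell cycle ended without replicate 1 (0.235) or 3 (0.253), with slide as a block (0.282) and under median centring (0.444).

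9cRA for 24 h raised cyp26c1 by 1.87 ± 0.22, cyp26a1 by 1.85 ± 0.22, cyp26b1 by 1.13 ± 0.17 and dhrs3a by 1.29 ± 0.14 (SD, n = 3). Smaller rises were those of dhrs3b (0.71), lratb.2 (0.64), lrata (0.42), rdh8a (0.36) and rdh12 (0.31), the last 2 at 0.17 and 0.04 after self-to-self subtraction. The flow-responsive transcription factor gene klf2a rose by 1.97 ± 0.17 (adjusted p = 1.63e-05), and the cytokine signalling suppressors socs1a and socs3a by 1.62 ± 0.33 and 1.47 ± 0.21. Of the same order were the rises of rhcga (2.02 ± 0.36), fkbp5 (1.74 ± 0.23), the orphan nuclear receptor gene nr4a1 (1.38 ± 0.10) and the photoreceptor gene guca1c (1.23 ± 0.25). The fin fold actinodin gene and1 fell by 1.15 ± 0.38 and the cartilage regulator sox9a fell by 0.80 ± 0.24 on the log2 scale. The lipoprotein receptor gene scarb1 (-0.78 ± 0.39), the cytoskeletal gene tln1 (-0.78), nudt21 (-0.97), hnrnpl (-0.86), cant1b (-0.86), rtn2a (-0.86), shq1 (-0.82) and dek (-1.01, with 1 of 4 other probes of the same sign) also fell.

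All 9 turnover and storage genes were called higher in the fit with the dye effect left in, and 9 adjusted over the list alone (adjusted p = 4.85e-11, and 0.0959 with an estimated correlation). Cartilage and bone genes were lower in 6 of 36 members, among them sox9a, col11a2 (-0.68) and epyc (-0.57). A total of 17 were lower and 2 higher adjusted over the list alone (adjusted p = 5.58e-05, and 0.0959 with an estimated correlation). Lens crystallins were higher in 16 of 50 members (crygm2d4 0.90, crygm2d10 0.87), with 20 higher and 2 lower adjusted over the list alone (adjusted p = 6.44e-08, and 0.62 with an estimated correlation). Ribosomal proteins were higher in 30 of 73 members and lower in 2, with rps14 at 0.94 and rps18 at 0.75. Of the 73, 35 were higher and 2 lower adjusted over the list alone (adjusted p = 6.22e-11, 0.403 with an estimated correlation and 0.209 after self-to-self subtraction). Phototransduction genes rose in 3 of 39 members, guca1c, pde6ha (0.72) and pdcb (0.42), and in 6 adjusted over the list alone (adjusted p = 0.0162, and 0.806 with an estimated correlation). Exocrine pancreas genes had a median of 0.44 with 1 of 26 members higher, the pancreatic progenitor gene ptf1a (0.28). Of the 26, 1 was higher adjusted over the list alone (adjusted p = 0.00307, and 0.806 with an estimated correlation).

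Lower as lists were cholesterol synthesis, with dhcr7 (-0.60) and hmgcra (-0.47) the 2 of 26 members called, and erythroid genes, with the haem synthesis gene urod (-0.33) the 1 of 21. So were cell cycle genes, with 0 of 39 called and a median of -0.20. The 3 adjusted p were 0.0101, 0.00619 and 0.000141, and 0.806, 0.719 and 0.806 with an estimated correlation. Adjusted over the list alone, 2, 5 and 0 of these members were lower. Xenobiotic metabolism, with a median of -0.16, had 2 of 72 members lower (cyp2p9 -0.71, ahr2 -0.53, the latter with 2 of 4 other probes of the same sign) and 2 higher (cyp2p7 0.51, sult2st3 0.50). Adjusted over the list alone 1 was higher (adjusted p = 0.0197, and 0.873 with an estimated correlation).

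With limma, 1709 genes changed at 24 h of 9cRA, 1131 higher and 578 lower, and 18 rose and 11 fell at least 2-fold. Of the calls 66.2% were higher, and 78.9% were with median centring. After self-to-self subtraction 17 genes were called, all higher, with slide as a block limma called 0, and with all spots in the background fit 409 were called. A fit of 9cRA 24 h alone called 301. Without 9cRA 24 h replicate 1, 2 or 3 the count was 448, 481 or 184, and without 9cRA 72 h replicate 2 it was 970. In the fit with slide as a block klf2a stood at 1.66 (adjusted p = 0.246), cyp26c1 at 1.38 (0.246) and fkbp5 at 1.74 (0.212), and in the 28 other alternatives these genes kept their calls, from 5.9e-06 upward. After self-to-self subtraction cyp26a1 (0.061) and socs1a (0.0527) were not called. Calls were lost in most alternatives for urod (25 of 29), cant1b and shq1 (17 of 29), dek (16 of 29, as small as -0.07), cyp2p9 (15 of 29) and lrata (19 of 28), and rdh12 lost its call in 10 of 29. Replicate 1 of 9cRA 24 h stood apart from the other 2, with list medians of 1.46 for exocrine pancreas and 0.51 for liver plasma proteins against 0.24 and -0.22, and -0.23 and -0.87. Without it the adjusted p of exocrine pancreas was 0.825. Leaving out replicate 3 ended the calls of xenobiotic metabolism (0.893), phototransduction (0.245), cholesterol synthesis (0.101) and erythroid (0.063), and leaving out replicate 2 those of phototransduction (0.104) and xenobiotic metabolism (0.129). With slide as a block the adjusted p was 0.742 for phototransduction, 0.957 with reversed direction for xenobiotic metabolism and 0.325 for erythroid, and over all alternatives of the 10 lists it ran from 4.14e-44 to 0.957.

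Genes of digestive enzymes were lower than in control after 72 h of 9cRA. The carboxypeptidase gene cpa5 fell by 2.72 ± 0.93, the amylase gene amy2a by 2.24 ± 0.91, the bile salt-stimulated lipase gene cel.1 by 1.95 ± 0.47 and the serine protease gene prss59.1 by 1.86 ± 0.90 on the log2 scale (SD, n = 3). The ratio of cpa4 was -1.76. The lipid carrier gene apoda.2 (-2.75 ± 0.72, adjusted p = 0.0308), the secretory calcium-binding phosphoprotein genes scpp9 (-2.46 ± 0.42) and odam (-1.94), endou (-1.96 ± 0.26) and the vitamin B12 carrier gene tcnba (-1.82) fell too. Retinoid-clearing genes were higher, with cyp26a1 at 1.3 ± 0.31 (adjusted p = 0.00664), cyp26c1 at 1.15 ± 0.24 and dhrs3a at 0.82 ± 0.10. The rises of lratb.2 (0.54), lrata (0.50) and rdh12 (0.38, and 0.12 after self-to-self subtraction) were called, while cyp26b1 (0.48, adjusted p = 0.134), dhrs3b (0.41, 0.0696) and rdh8a (0.17, 0.0872, the other probe of opposite sign) were not called. The transcription factor genes nfil3-5 (0.96 ± 0.04), jdp2b (0.94), nr4a1 (0.92 ± 0.41), sall1a (0.83) and egr3 (0.75) rose, as did fkbp5 (0.73 ± 0.12, the other probe of opposite sign) and the melanosome gene pmelb (0.72 ± 0.12).

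Of 26 exocrine pancreas genes, 14 fell and 0 rose, with a list median of -1.63, and 23 were lower and 1 higher adjusted over the list alone (adjusted p = 3.84e-13). Liver plasma proteins (median -0.79) had 1 of 37 members lower, the thyroid hormone carrier gene ttr (-1.60), and 25 lower and 1 higher adjusted over the list alone (adjusted p = 1.44e-11). The intestine list (median -0.66) had 0 of 25 members called and 14 lower adjusted over the list alone (adjusted p = 9.59e-09). Xenobiotic metabolism genes fell in 4 of 72 members, gsto2 (-1.75), cyp3a65 (-1.2), cyp3c3 (-0.87) and cyp2v1 (-0.30, and 0.09 under median centring), with 25 lower and 1 higher adjusted over the list alone (adjusted p = 1.38e-10). The adjusted p of each of these 4 lists was 0.364 with an estimated correlation. Fatty acid catabolism and PPAR targets were lower in 2 of 37 members, among them the mitochondrial acyl-CoA dehydrogenase gene acadm (-0.81), and their median of -0.19 flipped to 0.16 under median centring. A total of 13 were lower and 2 higher adjusted over the list alone (adjusted p = 0.000142, and 0.364 with an estimated correlation). Fin and epidermal structural genes were lower in 7 of 34 members, led by and2 (-1.15), and1 (-1.07) and tp63 (-0.75), and the median of -0.39 flipped to 0.07 under median centring, where all genes stood at 0.15. Of the 34, 16 were lower and 2 higher adjusted over the list alone (adjusted p = 1.71e-07, and 0.364 with an estimated correlation). The heart muscle list was lower with a median of -0.45, although its 1 called member of 18, actc1a, rose (0.36, with 1 of 3 other probes of the same sign). Of the 18, 10 were lower and 1 higher adjusted over the list alone (adjusted p = 9.68e-06, and 0.364 with an estimated correlation). Bile acid genes had a median of -0.30, 0 of 9 members called and 1 lower adjusted over the list alone (adjusted p = 0.0128, and 0.401 with an estimated correlation).

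Turnover and storage genes were higher in 6 of 9 members, and in 9 adjusted over the list alone (adjusted p = 2.87e-08). The anterior and central hox genes rose in 8 of 24 members, hoxc4a by 0.59, hoxb5b by 0.58 and hoxd3a by 0.46, and in 14 adjusted over the list alone (adjusted p = 1.48e-06). Phototransduction genes rose in 5 of 39 members, among them guca1c (0.65) and the red opsin gene opn1lw2 (0.57, the other probe of opposite sign), and in 14 adjusted over the list alone (adjusted p = 5.06e-08). Retinoid binding proteins had 3 of 11 members higher, rbp5 (0.60), rbp7b (0.51) and crabp1b (0.48, and -0.01 after self-to-self subtraction), and rbp2a lower (-1.06), with the same numbers adjusted over the list alone (adjusted p = 0.0133). Pigment genes rose in 3 of 15 members (pmelb, pts 0.42, atp6v0ca 0.34, the other probes of pts and atp6v0ca of opposite sign), with 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.0142). Ribosomal proteins rose in 13 of 73 members and fell in 2 (rps18 0.81, and rpl8 0.75, both other probes of opposite sign), with 20 higher and 4 lower adjusted over the list alone (adjusted p = 9.26e-06). The adjusted p of each of these 6 lists was 0.364 with an estimated correlation. Neuronal and glial genes rose in 7 of 55 members, including neurod1 (0.63), the glutamate transporter gene slc1a2b (0.46) and snap25a (0.45, with 1 of 3 other probes of the same sign). Of the 55, 14 rose adjusted over the list alone (adjusted p = 6.8e-05, and 0.48 with an estimated correlation).

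With limma, 1079 genes changed at 72 h of 9cRA, 722 higher and 357 lower, and 2 rose and 59 fell at least 2-fold. Of the calls 66.9% were higher, and 84.0% were with Agilent's log ratio and 91.6% of 8387 calls with median centring, where the median of all genes stood at 0.153 against 0.017. Subtracting the self-to-self mean left 0 limma calls, with 1437 genes at an unadjusted p under 0.05 and 92.1% of the calls keeping their sign, and with slide as a block 491 genes were called. In that block fit cyp26a1 (1.04, adjusted p = 0.0377) and cyp26c1 (0.93, 0.018) kept their calls, while cpa5 (-2.91, 0.1) and amy2a (-2.47, 0.0761) lost them. After self-to-self subtraction all 4 were at 0.711, the highest of ranges that began at 0.000228, 3.26e-05, 0.00935 and 0.00677. The calls of rbp2a (18 of 29 alternatives), cyp3c3 (16 of 29), odam (16 of 28) and cyp2v1 (15 of 29, and reversed in 1) were lost more often than kept. Without 9cRA 72 h replicate 1, 2 or 3 the count was 1852, 40 or 109, without 9cRA 24 h replicate 2 it was 455, and without RA 24 h replicates 1, 2 and 3 it was 703, 523 and 536. Without RA 72 h replicate 3 it was 2455, and without the slide of the other scan day, an alternative chosen after seeing the data, 3895. The list of bile acid genes lost its call without 9cRA 72 h replicate 1 (adjusted p = 0.0608), with slide as a block (0.276) and under median centring (0.106). Median centring also ended the calls of the fin (0.365) and fatty acid lists (0.694), and self-to-self subtraction ended and reversed that of ribosomal proteins (0.168). Over their alternatives the 15 lists ran from an adjusted p of 1.46e-20 to 0.694.

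**Figure D2:**
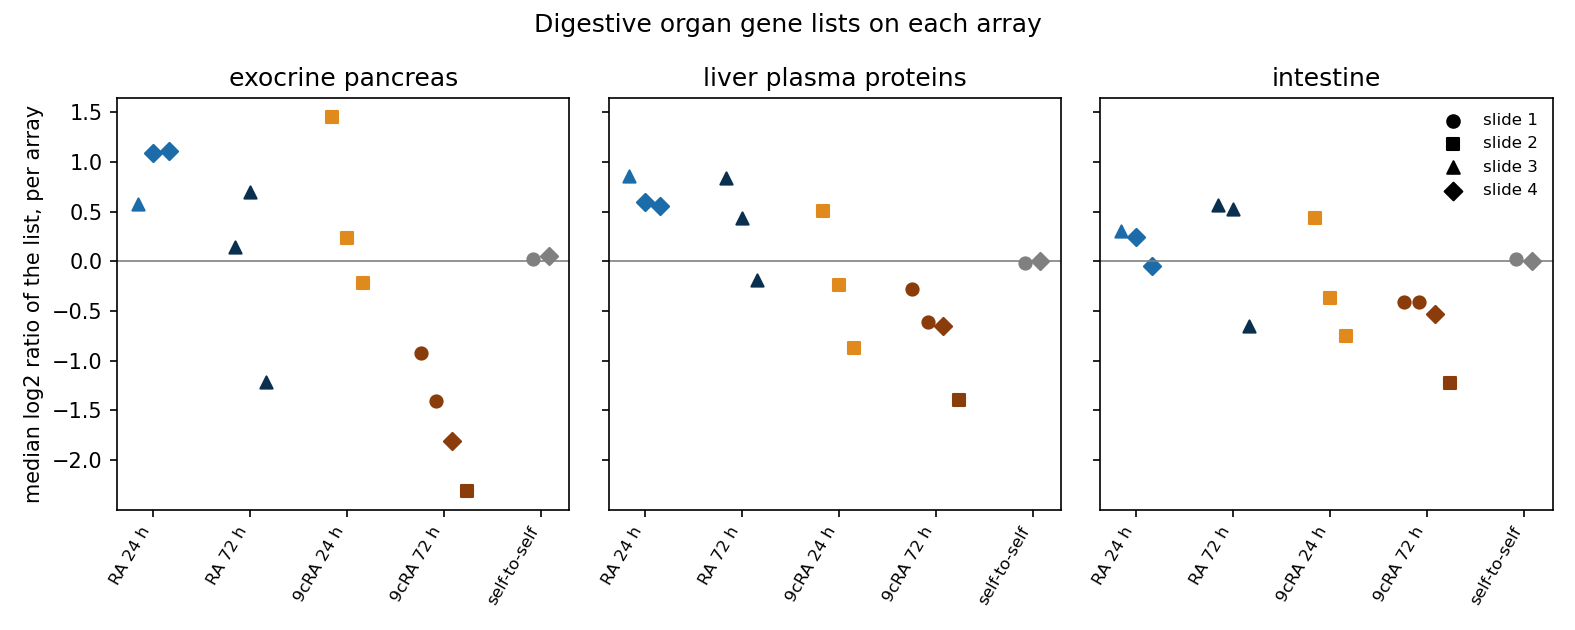
Median log2 ratio of treated over control pool (y axis) of the exocrine pancreas, liver plasma protein and intestine lists on each array, by group, with points marked by slide. All arrays of 9cRA 72 h had pancreas medians at or below -0.92, against 0.57 to 1.12 in RA 24 h, and the self-to-self arrays were at 0.02 and 0.06.

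Between the compounds at 24 h, limma called 0 of 22282 genes, with 1904 at an unadjusted p under 0.05 and a lowest adjusted p of 0.437. The 95% interval of RA minus 9cRA lay within 2-fold for 21284 genes (95.5%) and within 1.5-fold for 79.3%. For cyp26a1 the difference was 0.05 (interval -0.56 to 0.66), for cyp26c1 0.05 (-0.32 to 0.41), for cyp26b1 0.28 (-0.28 to 0.85) and for dhrs3a 0.00 (-0.44 to 0.44). Intervals that excluded 0 before adjustment included those of klf2a at -0.93 (-1.29 to -0.57, adjusted p = 0.459), socs1a at -0.84 (-1.37 to -0.31), socs3a at -0.61 (-0.89 to -0.32) and leg1.1 at 1.93 (1.08 to 2.79). Among the genes of lowest p, chosen after their values were seen, were rnd2 at -0.60 (-0.79 to -0.41) and the liver protein gene ahsg2 at 1.70 (1.00 to 2.39, adjusted p = 0.489).

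As lists, several tissue groups differed at 24 h, with 0 members called in any of them and an adjusted p of 0.81 with an estimated correlation for each. Higher in RA were liver plasma proteins (median difference 0.75, adjusted p = 7.21e-20, 7 members adjusted over the list alone), erythroid genes (0.25, 1.85e-07, 4 members adjusted over the list alone) and heart muscle (0.33, 2.89e-05, 1 member). Lens crystallins (0.18, 1.43e-05), xenobiotic metabolism (0.22, 2.98e-05), fin and epidermal structural genes (0.23, 0.000318), intestine (0.34, 0.00102) and bile acid genes (0.26, 0.0311) were also higher. Phototransduction (-0.17, 0.00234) and neuronal and glial genes (-0.12, 0.0146) were lower in RA, and their medians flipped to 0.06 and 0.05 under median centring, still below the median of all genes at 0.085 (adjusted p = 0.708 for both, and 0.09 for bile acid genes). In the other 7 lists 0 members were called adjusted over the list alone. With slide as a block the erythroid list kept its call (0.000534), liver plasma proteins were at 0.304, lens crystallins at 0.816, xenobiotic metabolism at 0.748, phototransduction at 0.703 and neuronal and glial genes at 0.126. The fin (0.675), heart muscle (0.829), intestine (0.569) and bile acid lists (0.944) turned direction. Leaving out 9cRA 24 h replicate 3 ended the calls of fin and epidermal structural genes (0.0775), intestine (0.392), xenobiotic metabolism (0.122), bile acid genes (0.376), neuronal and glial genes (0.38) and phototransduction (0.122). Without RA 24 h replicate 1 bile acid genes were at 0.14 and phototransduction at 0.213. Without RA 24 h replicate 2 bile acid genes were at 0.0735 and neuronal and glial genes at 0.155, and without 9cRA 24 h replicate 2 they were at 0.128 and 0.0839. The range over all alternatives of these lists was 2.56e-36 to 0.944, and no slide held both compounds at this time.

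At 72 h the compounds differed in genes of the liver and gut. RA minus 9cRA was 2.87 ± 0.51 (SE) for igfbp1b (adjusted p = 0.00946), with group means of 2.09 in RA and -0.78 in 9cRA. It was 2.32 ± 0.54 for the iron hormone gene hamp (0.85 and -1.46) and 2.41 ± 0.60 for uox (0.97 and -1.44). For cyp7a1 it was 2.26 ± 0.73, cyp7a1 encoding the rate-limiting enzyme of bile acid synthesis (0.43 and -1.84 in the groups, with 1 of 2 other probes of the same sign). The elastase gene cela1.3 (2.44), apoda.2 (2.78), the interferon-induced gene ifitm1 (2.56 ± 0.49, 1.01 and -1.56), endou (2.5), scpp9 (2.46) and ces2a (2.4) were also higher in RA. The neuronal activity genes fosab (-1.64 ± 0.32, -1.07 and 0.57), npas4a (-1.56 ± 0.22, -0.95 and 0.61) and egr4 (-1.46 ± 0.19, -1.12 and 0.35) were lower in RA. So were the fatty acid carrier gene fabp4b (-2.02 ± 0.51, -0.80 and 1.23), rn7sk (-1.96 ± 0.40, -2.58 and -0.62) and nucks1a (-1.74). The ratios of ubap2a (-1.65), ptenb (-1.59), tmem208 (-1.47, and 0.10 with slide as a block) and col4a5 (-1.53, the other probe of opposite sign) were also lower in RA.

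Higher in RA were 18 of 37 liver plasma proteins, led by uox, agxta (1.99), apoa4b.2 (1.92) and apoa2 (1.90), and 25 adjusted over the list alone (adjusted p = 8.84e-10). So were 8 of 26 exocrine pancreas genes (cpa5 2.77, amy2a 2.19), and 14 adjusted over the list alone (adjusted p = 2.08e-06). Of 25 intestine genes 5 were higher, among them the gluconeogenesis gene pck1 (2.08) and the apolipoprotein gene apoa4a (1.29), and 5 adjusted over the list alone (adjusted p = 7.85e-05). Of 9 bile acid genes 3 were higher (cyp7a1, slc51a 1.17), and 4 adjusted over the list alone (adjusted p = 0.00252). Xenobiotic metabolism had 22 of 72 members higher and 1 lower (gsto2 2.02, cyp2n13 1.88) and 29 and 3 adjusted over the list alone (adjusted p = 4.15e-08). Heart muscle had 8 of 18 members higher (myl7 1.44, tnnt2a 1.37, nppa 1.15) and 13 adjusted over the list alone (adjusted p = 0.00011). Fin and epidermal structural genes had 8 of 34 higher (ppl 1.41, its 3 other probes of opposite sign, and cldne 1.05) and 10 adjusted over the list alone (adjusted p = 0.000278). The adjusted p of each of these lists was 0.676 with an estimated correlation. Neuronal and glial genes were lower in RA in 20 of 55 members and higher in 1 (gad2 -0.89, the glutamate receptor genes grin1a -0.87 and gria2b -0.83). Adjusted over the list alone 22 were lower and 1 higher (adjusted p = 0.000264, and 0.676 with an estimated correlation). Cell cycle genes were lower in 8 of 39 members (ccna2 -0.64, with 1 of 2 other probes of the same sign, and aurkb -0.58), and in 8 adjusted over the list alone. The direction turned with slide as a block (0.16, against adjusted p = 0.000529 without it, and 0.788 with an estimated correlation).

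Smaller shifts toward RA were called in oxidative and heat stress genes, where 8 of 38 members were higher and 1 lower (nqo1 1.47, and hmox1a 1.62, which was 0.03 with slide as a block), and in innate immunity genes, 9 of 34 and 2 lower (hamp, irg1l 1.29, ptgs2b -1.28). Fatty acid catabolism and PPAR targets had 6 of 37 members higher and 3 lower (ucp2 1.00, and fabp7a -0.91, which was 0.10 with slide as a block). Erythroid genes had 5 of 21 higher (hbae3 0.90, hbbe2 0.80), and lens crystallins 2 of 50 higher and 2 lower (cryaa 0.54, and crygs1 -0.80, at -0.04 with that block). In this order the adjusted p were 0.0219, 0.0219, 0.00774, 0.0491 and 0.0472, and 0.676 with an estimated correlation for each except lens crystallins at 0.817. Adjusted over the list alone, 8, 9, 10, 5 and 0 members were higher and 1, 2, 3, 0 and 0 lower. Leaving out 9cRA 72 h replicate 3 ended the calls of innate immunity (0.0746), fatty acid catabolism and PPAR targets (0.0746), erythroid (0.249) and lens crystallins (0.553). Leaving out RA 72 h replicate 1 ended those of innate immunity (0.096), erythroid (0.152) and lens crystallins (0.288), and leaving out RA 72 h replicate 2 those of oxidative and heat stress (0.0713) and erythroid (0.147). The erythroid call was lost in 10 of 17 alternatives, with 0.0878 without 9cRA 72 h replicate 2, 0.0512 and 0.0524 without RA 24 h replicates 1 and 2, 0.0521 and 0.0548 without 9cRA 24 h replicates 1 and 3, and 0.0589 with all spots in the background fit. Without RA 24 h replicates 1 and 2 the lens crystallins list was at 0.0512 and 0.0547.

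With limma, 5397 genes differed between the compounds at 72 h, 2392 higher and 3005 lower in RA, with 368 and 266 of them at least 2-fold apart. A fit of these 2 groups alone called 1238. Of the calls 44.3% were higher in RA, and 62.3% with median centring. No slide held both compounds at 72 h, and with slide as a block limma called 0 genes while a median share of 0.653 of the log2 difference was left (25th to 75th percentile 0.400 to 0.902). The differences of igfbp1b (2.08), rn7sk (-0.76) and egr4 (-1.10) were then each at an adjusted p of 0.803, the highest of ranges from 0.000872, 0.00464 and 0.000285. The calls of cyp7a1, cpa5 and amy2a were lost in 17 of 28 alternatives each and that of apoa2 in 16 of 28. The count was 265, 2031 or 8754 without RA 72 h replicate 1, 2 or 3, 1381 without 9cRA 72 h replicate 1, 1494 without its replicate 2, and 392 without the slide of the other scan day. Slide as a block ended the calls of heart muscle (0.0737), fin and epidermal structural genes (0.436), bile acid genes (0.411), innate immunity (0.104) and cell cycle (0.16). Cell cycle was at 0.115 without RA 72 h replicate 3 and at 0.152 under median centring. The range over all alternatives of the 14 lists was 3.96e-17 to 0.817.

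Between 72 h and 24 h of RA, 4 genes differed with limma, all lower at 72 h, and with the replicate number as a block 29 did, 20 lower and 9 higher, and 5 lists in place of 4. The muscle phosphatase regulator gene ppp1r27b went from 0.94 to -0.30, a difference of -1.24 ± 0.16 (SE, adjusted p = 0.0463). The mitochondrial carrier gene sfxn4 went from 0.28 to -0.48, a difference of -0.75 ± 0.09 (adjusted p = 0.0463). Within the slide that holds RA 24 h replicate 1 and the 3 replicates of RA 72 h, the differences were -1.27 and -0.74. Both differences had an adjusted p of 0.447 with slide as a block, and the 2 calls were lost in 20 of 29 alternatives. The fit within the slide has 1 array of RA 24 h, assumed to vary like the others, so its adjusted p of 0.985 decides nothing. The other 2 genes have no gene name. The list of lens crystallins was lower at 72 h by a median of -0.39 (adjusted p = 1.88e-15, and 0.77 with an estimated correlation; -0.41 within the slide). Of its 50 members 0 were called, and 25 were lower adjusted over the list alone. Exocrine pancreas genes were lower (-1.09, adjusted p = 0.00111; -0.66 within the slide), as were ribosomal proteins (-0.21, adjusted p = 0.00185; -0.16 within the slide), which flipped to 0.08 under median centring where the median of all genes stood at 0.127 against -0.012. Cholesterol synthesis was higher (0.18, adjusted p = 0.0362; 0.52 within the slide). The adjusted p of these 3 lists was 0.968 with an estimated correlation, and 1 cholesterol synthesis gene and 0 in the other 2 lists were called adjusted over the list alone. Over alternatives of the 4 lists the adjusted p ran from 2.75e-22 to 0.968. Exocrine pancreas lost its call without RA 72 h replicate 3 (0.671) and with slide as a block (0.328), and ribosomal proteins without RA 72 h replicate 2 (0.0621). The list of cholesterol synthesis lost it without RA 24 h replicate 1 (0.809), RA 72 h replicate 2 (0.526) or 9cRA 72 h replicate 1 (0.0509) and under median centring (0.0604). The count was 733 without RA 72 h replicate 3, 24 without 9cRA 72 h replicate 1, 1 without RA 72 h replicate 1, and 0 without each of the other replicates. It was 89 without the slide of the other scan day and 0 in limma with slide as a block, beside 3206 genes at an unadjusted p under 0.05 without the block. The log2 differences within the slide correlated with those over all slides at r = 0.814 across genes.

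Between 72 h and 24 h of 9cRA, 14 genes differed, 12 lower and 2 higher at 72 h. The cytokine signalling suppressors socs1a and socs3a went from 1.62 to -0.31 and from 1.47 to 0.23, differences of -1.93 ± 0.24 and -1.24 ± 0.13 (SE; adjusted p = 0.0257 and 0.00876). The transcription factor gene klf2a went from 1.97 to 0.14 (-1.82 ± 0.16, adjusted p = 0.00333), rhcga from 2.02 to 0.15 (-1.87 ± 0.26), pfkfb4b from 1.12 to 0.07 (-1.04) and fkbp5 from 1.74 to 0.73 (-1.02). The signalling regulator genes cisha (-0.94) and nfkbiab (-0.62), the clock repressor gene nr1d2a (-0.92) and the survival gene mcl1b (-0.72) were lower too. Within the second slide the differences were -2.44 for socs1a, -1.57 for klf2a, -1.85 for rhcga and -1.14 for socs3a. In RA the difference over time was -0.62 for klf2a (adjusted p = 0.167), -0.58 for socs1a (0.305), -0.59 for socs3a (0.119) and -0.21 for rhcga (0.745), and none of these passed the interaction test.

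**Figure D3:**
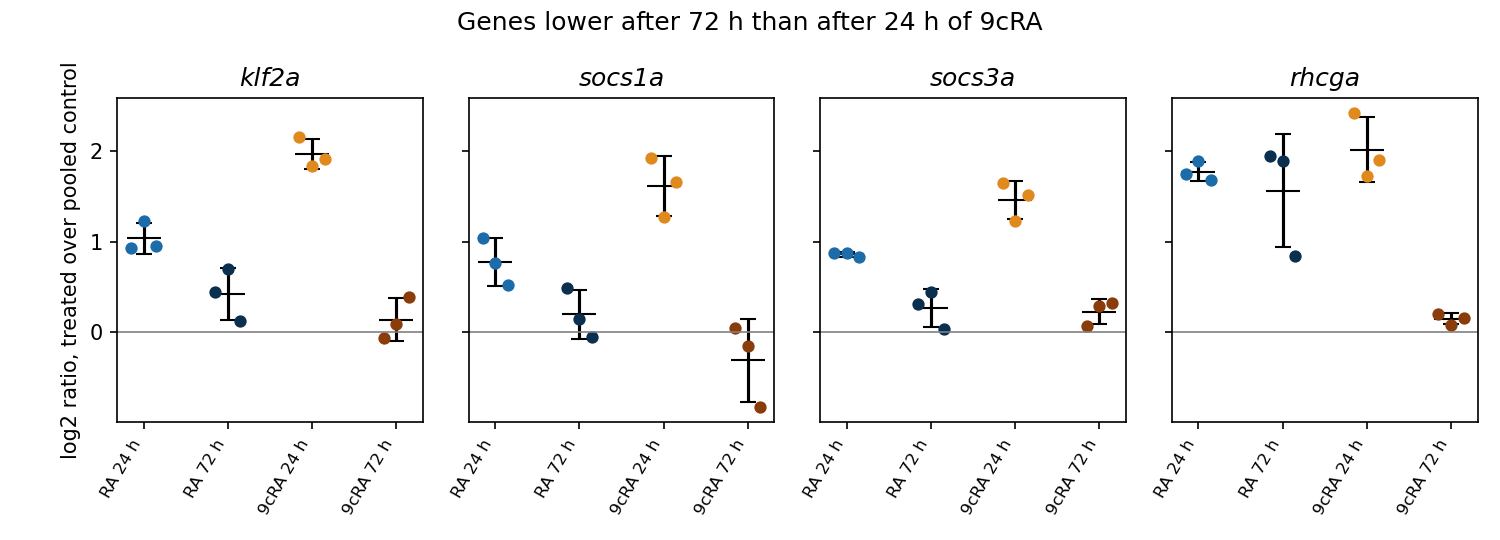
Log2 ratio of treated embryos over the control pool (y axis) for klf2a, socs1a, socs3a and rhcga in the 4 groups; dots are replicates, bars the mean of 3 and whiskers the SD.

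In 9cRA 11 lists were lower and 8 higher at 72 h than at 24 h. Exocrine pancreas genes had the largest shift, with a median of -2.02 (adjusted p = 3.51e-24; -2.70 within the second slide), 0 members called and 24 of 26 lower adjusted over the list alone. Lens crystallins were lower by -0.33 (6.75e-17, 17 members adjusted over the list alone; -0.56 within the slide). Innate immunity genes were lower by -0.17, with socs3a and nfkbiab the 2 of 34 members called (9.36e-05; 4 lower and 1 higher adjusted over the list alone; -0.21 within the slide). Turnover and storage genes were lower by -0.29, which flipped to 0.02 under median centring (adjusted p = 0.00179; -0.21 within the slide). Cartilage and bone genes were higher by 0.10 (0.00923; -0.01 within the slide; 6 higher and 1 lower adjusted over the list alone), and pigment genes by 0.06 (0.0226; 0.16 within the slide). The adjusted p of these 6 lists was 0.4 with an estimated correlation. Liver plasma proteins (-0.55, 2.99e-07; -1.18 within the slide), fin and epidermal structural genes (-0.29, 6.17e-06; -0.45), and intestine (-0.40, 0.000291; -0.86) were lower. Heart muscle (-0.33, 0.0022; -0.55), xenobiotic metabolism (-0.18, 9.36e-05; -0.34), bile acid genes (-0.32, 0.0422) and ribosomal proteins (-0.09, 0.00359; 0.15 under median centring) were also lower. Cell cycle genes (0.30, 4.39e-08; 0.46 within the slide), anterior and central hox genes (0.16, 0.00359; 0.26), posterior hox genes (0.13, 0.00969; 0.18) and cholesterol synthesis (0.19, 0.00765; 0.24) were higher. The adjusted p of these 11 lists was 0.472 with an estimated correlation. Phototransduction (0.13, 0.0124; 0.22) and neuronal and glial genes (0.12, 0.00259; 0.16) were higher, at an adjusted p of 0.55 and 0.519 with an estimated correlation. When adjusted over the list alone, 1 turnover gene was lower, 2 pigment genes and 1 cholesterol synthesis gene were higher, and the lists given without a count had 0.

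The time count in 9cRA was 1 with slide as a block, 2 with all spots in the background fit, 5 with Agilent's log ratio, and 0 with median centring, where the median of all genes stood at 0.144 against 0.014. Within the second slide, where 9cRA 72 h has a single array and the test decides nothing, it was 0 in limma, beside 2113 genes at an unadjusted p under 0.05 over all slides. It was 1 without 9cRA 24 h replicate 1 or 3 or 9cRA 72 h replicate 2, 2 without 9cRA 72 h replicate 3, and 4 without 9cRA 72 h replicate 1. It was 8 without replicate 2 of 9cRA 24 h or of RA 24 h, and 5 without RA 24 h replicate 3. With slide as a block the adjusted p was 0.133 for klf2a, 0.0697 for socs1a and 0.177 for socs3a, in ranges of 0.000814 to 0.313, 0.00559 to 0.313 and 0.00223 to 0.363. Over 29 alternatives fkbp5 lost its call in 18, pfkfb4b, cisha, nr1d2a and mcl1b in 16 each, and rhcga and nfkbiab in 15 each. The call of klf2a held without each replicate, and those of socs1a and socs3a ended without 9cRA 24 h replicate 1 (0.114 and 0.0569) or 3 (0.129 and 0.0887) or 9cRA 72 h replicate 2 (0.146 and 0.0687), and that of socs1a also without 9cRA 72 h replicate 3 (0.0738). Without 9cRA 24 h replicate 1 the calls of heart muscle (0.31), intestine (0.516), xenobiotic metabolism (0.266), phototransduction (0.516), neuronal and glial (0.296) and bile acid genes (0.589) ended. Without 9cRA 72 h replicate 3 those of the anterior and central hox genes, heart muscle, intestine and ribosomal proteins (0.1 each), phototransduction (0.217), bile acid genes (0.122) and pigment (0.0703) ended, and pigment was at 0.0568 without 9cRA 72 h replicate 2. Cartilage and bone was at 0.103 without 9cRA 24 h replicate 3 and at 0.0934 without 9cRA 72 h replicate 1, cholesterol synthesis at 0.124 and 0.0537, and posterior hox genes were at 0.155 without 9cRA 24 h replicate 2. Ribosomal proteins were at 0.151 without 9cRA 24 h replicate 3. Under median centring bile acid genes and cholesterol synthesis were at 0.0729 and posterior hox genes at 0.0828. With slide as a block cartilage and bone was at 0.307, cholesterol synthesis at 0.0924, bile acid genes at 0.105, and pigment at 0.0696. The list of retinoic acid turnover and storage was at 0.172 with that block, at 0.136 under median centring and at 0.0571 with all spots. Over all alternatives the lists ran from 3.4e-30 to 0.983, and differences within the slide correlated with those over all slides at r = 0.842 across genes.

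The time course differed between the compounds in lists and in 0 single genes with limma (2359 at an unadjusted p under 0.05). The change from 24 h to 72 h was higher in RA than in 9cRA for exocrine pancreas (0.96, adjusted p = 8.67e-06), intestine (0.45, 0.017), xenobiotic metabolism (0.28, 0.000296) and fatty acid catabolism and PPAR targets (0.26, 0.0108). It was lower for cell cycle (-0.24, 0.0034) and neuronal and glial genes (-0.22, 0.00861). No member of these 6 lists was called, 1 gene of the fatty acid list was higher adjusted over the list alone, and their adjusted p was 0.944 with an estimated correlation, the highest of a range of 7.46e-13 to 0.944 over the alternatives. The call of intestine ended without 9cRA 24 h replicate 1 (0.69), 9cRA 72 h replicate 3 (0.418) or RA 72 h replicate 1 (0.236) or 2 (0.231), and that of exocrine pancreas held without each replicate. Leaving out 9cRA 24 h replicate 1 also ended the calls of xenobiotic metabolism (0.0976), fatty acid catabolism and PPAR targets (0.0976) and neuronal and glial genes (0.204), and leaving out 9cRA 72 h replicate 3 these 3 (0.0553, 0.171 and 0.103) and cell cycle (0.135). Cell cycle was also at 0.343 without RA 72 h replicate 3, at 0.0782 without RA 24 h replicate 2 and at 0.319 with slide as a block. Neuronal and glial genes and cell cycle were at 0.0596 without RA 72 h replicate 1, and neuronal and glial genes and the fatty acid list at 0.0816 without RA 72 h replicate 2.

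Both compounds were compared with pooled control RNA. Where the pool was the same, its chance values add to any excess over independent lists. At 24 h RA and 9cRA shared 826 genes called higher and 419 called lower, where independent lists of these sizes give 143 and 71.7, and 0 genes were called in opposite directions. The log2 ratios correlated at r = 0.672 (rho = 0.659) across genes with a covariance of 0.0432. In 20 simulated draws of unchanged groups r was 0.502 and the covariance 0.0134, with 1.95 and 1.9 shared genes. A pool of 3 replicates was assumed, and r depends on it. With the self-to-self mean added as a dye effect r was 0.727 and the covariance 0.0356. Per group 3222 and 3243 genes were called, with 994 and 705 shared. At 72 h 375 genes were shared higher and 139 lower, where independent lists give 152 and 82.7, and 39 were opposite. The correlation was 0.159 (rho = 0.180) and the covariance 0.0158, beside simulated values of 0.503 and 0.0135, and 0.727 and 0.0356 with the dye effect. After self-to-self subtraction 14 genes were shared at 24 h and 0 at 72 h, with r of 0.592 and 0.0123 and covariances of 0.0315 and 0.0011. The control RNA was pooled and could not be split.

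On the 2 self-to-self arrays 1 of 22281 genes differed from 0 with limma, with 1841 at an unadjusted p under 0.05. The second self-to-self array correlated with the 13 treated arrays at r of 0.0317 to 0.546 (median 0.339) and the first at r of -0.0418 to 0.426 (median 0.066), across genes.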

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

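The change from 24 h to 72 h differed between RA and 9cRA in 6 gene lists by a test of the difference itself. Exocrine pancreas (adjusted p = 8.67e-06), intestine (0.017), xenobiotic metabolism (0.000296) and fatty acid catabolism and PPAR targets (0.0108) had a lower change over time in 9cRA than in RA, and cell cycle (0.0034) and neuronal and glial genes (0.00861) a higher one. With an estimated correlation each was at an adjusted p of 0.944. Within a compound the effect against control differed between the 2 times for 4 genes in RA (29 with a replicate block) and 14 in 9cRA, and for 4 lists in RA (1 higher and 3 lower at 72 h) and 19 in 9cRA (8 higher and 11 lower). By that estimate the adjusted p of these lists was 0.77 to 0.968 in RA and 0.4 to 0.55 in 9cRA.

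The counts of genes were set against other splits of the same replicates, a test written before the results were seen, over the 22105 genes measured on all replicates. With 6 replicates there are 10 splits, too few for a share under 0.05. For RA minus 9cRA at 72 h 1 of 10 splits, the real one, called as many genes as its 5361, and the highest other split called 0. For RA minus 9cRA at 24 h 10 of 10 splits reached the real count of 0, and the highest other count was 0. For time in 9cRA 1 of 10 splits reached 14, and the highest other called 0. For time in RA 2 of 10 reached 4, and the highest other split called 94, several times the real count, which points to a structure of the samples. That split set RA 24 h replicate 1 with RA 72 h replicates 1 and 3 and so kept a same-numbered pair together, as 6 of the 10 splits do. Of the 4 splits that part all 3 pairs, 1, the real one, reached 4, and with the replicate block 1 reached the real count of 28, with 0 in the highest other (141 where a pair was kept together). For the interaction 100 of 100 drawn splits reached the real count of 0, as any split does, and the highest called 7127. What that split follows was not examined, and chance was not excluded.

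The tests of the next 3 patterns were all written after the results were seen. The first is the breadth of the change at 72 h of RA, with 9845 genes called. Subtracting the self-to-self mean left a median share of 0.840 of the log2 ratio (25th to 75th percentile 0.618 to 1.03). Its 2 arrays correlated at r = 0.167, so a dye effect as the whole cause stays open. The calls fell from 9845 to 1808 as the median standard error went from 0.0926 to 0.147 and the median size from 0.406 to 0.349, and the 2 contributions were not separated. With slide as a block a median share of 0.773 was left (0.526 to 1.01), at a median size of 0.327 and a standard error of 0.194, and 0 genes were called. All 3 replicates lay on 1 slide that a single array of another group ties to the rest, so slide and a broad effect of RA cannot be told apart.

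The second pattern is the likeness of 9cRA 24 h replicate 1 to the RA arrays. Its score on the 50 genes that best part the other 24 h replicates was 0.387. RA 24 h ran from 0.296 to 0.415, and the rest of its group was at 0.814 and 0.958. It lay above every RA 24 h replicate for rhcga (2.42), klf2a (2.15), socs1a (1.92), socs3a (1.64) and guca1c (1.03). The other 5 of the 10 genes that rose most in 9cRA 24 h without it cannot tell. There another of its group was also under the highest RA value. RA 24 h RNA was not excluded. A component shared with the second self-to-self array is argued against, since the correlation with the mean of RA 24 h was 0.792 and stayed at 0.722 once that array was regressed out.

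The third pattern is the lower level of exocrine pancreas genes after 72 h of 9cRA. A control pool rich in pancreatic RNA on all arrays is argued against by list medians over 0 in 7 of 12 replicates. Slide or scan day is argued against by medians of -0.921 or lower on every array of the group, which lay on 3 slides, and by a value under that of each 9cRA 24 h replicate within the slide that holds both. The state of the digestive organs in a dish, whatever the compound, has the values it needs, because RA 72 h replicate 3 (-1.21) lay in the range of 9cRA 72 h and deviations of the pancreas and liver medians from their group means correlated at r = 0.826 over 12 replicates, but lens crystallins and heart muscle moved with the liver list as closely (r = 0.945 and 0.934), so the shared movement is not one of digestive organs alone. The label of RA 72 h replicate 3 is open to doubt, though fkbp5 was at 2.42 as in RA 72 h. Its r with arrays of 9cRA 72 h was 0.157 to 0.702. An effect of 9cRA on the pancreas was not excluded, and both may act.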

How the results depend on the processing

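The direction and the call held in all 29 alternatives for 4 of 286 gene results, the rises of fkbp5, cyp26c1, cyp26a1 and dhrs3a after 24 h of RA, at adjusted p of up to 0.0108, 0.00498, 0.03 and 0.0403. Signal over background, median 138 to 241 against 50 to 53 units in the treated channel, limits what was tested, and 3 replicates limit the precision. Unless stated, the cause of a moved value was not tested. Subtraction of the self-to-self mean cannot be run for time and compound contrasts, where it cancels.

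With Agilent's log ratio 2 and 5 genes differed with time in RA and 9cRA, and actc1a after 24 h of RA was at -0.025. Median centring called 15518 genes at 72 h of RA and 8387 at 72 h of 9cRA, 0 with time in either compound (limma, against 3206 and 2113 at an unadjusted p under 0.05 in the loess fit), 4161 on the self-to-self arrays and 6716 shared at 72 h. It turned the sign of rdh8a (0.573), mcm6 (0.095), mcm7 (0.234), ube2c (0.139) and aurkb (0.121) after 72 h of RA and cyp2v1 (0.092) after 72 h of 9cRA, but the median of all genes stood at 0.28 and 0.153, over all of these except rdh8a. It also turned the lists cell cycle at 72 h of RA (adjusted p = 0.444) and ribosomal proteins with time in 9cRA (0.983). The stricter filter, the authors' series table, and either array of 9cRA 72 h replicate 2 alone each left 0 genes with time in RA. With every probe on its own, and so more tests, 8955 and 15936 probes changed at 24 h and 72 h of RA, 1 and 9141 differed between compounds at 24 h and 72 h, and 23 with time in 9cRA. Trend and robust eBayes called 14 and 6 with time in RA and 9cRA. A fold of at least 1.5, a stricter demand by construction, left 1020 and 2496 genes in RA and 287 and 253 in 9cRA at 24 h and 72 h, and 2623 between compounds at 72 h.

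Subtracting the self-to-self mean left 62 and 1808 genes in RA and 17 and 0 in 9cRA at 24 h and 72 h, and 14 and 0 shared. It reversed rps18 at 24 h of RA (-0.007), rdh8a (-0.014) and crabp1b (-0.01) at 72 h of 9cRA, and ribosomal proteins at 72 h of 9cRA (adjusted p = 0.168). With slide as a fixed block 32 and 0 genes changed in RA and 0 and 491 in 9cRA at 24 h and 72 h, 0 differed between compounds at 72 h, and 0 and 1 with time in RA and 9cRA. It reversed mcm6 (0.079) and apoeb (-0.184) at 72 h of RA, and tmem208 (0.099), ccna2 (0.042), kif11 (0.009), pdk2b (-0.111) and fabp7a (0.101) between compounds at 72 h. Among lists it reversed cell cycle at 72 h of RA (adjusted p = 0.282) and between compounds at 72 h (0.16), xenobiotic metabolism at 24 h of 9cRA (0.957), and bile acid genes (0.944), fin and epidermal structural genes (0.675), heart muscle (0.829) and intestine (0.569) between compounds at 24 h. As a random block slide had a consensus correlation of -0.00248 and left 0 genes with time in RA. Fits of only the groups compared, with fewer samples, called 3866 genes at 72 h of RA, 301 at 24 h of 9cRA, 1238 between compounds at 72 h, and 0 and 1 with time in RA and 9cRA.

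Chosen after seeing the data, all spots in the background fit gave 409 genes at 24 h of 9cRA and 2 with time in 9cRA. Comparisons within 1 slide, with a single array in 1 arm, gave 0 with time in RA and 0 in 9cRA and decide nothing. Without the slide of the other scan day 3895 genes changed at 72 h of 9cRA, 392 differed between compounds at 72 h, 89 and 100 with time in RA and 9cRA, and 1 in the interaction.

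Only RA 24 h and RA 72 h were treated as paired by number, and chance was not excluded. Over all groups 9 of 18 same-number pairs correlated over 0.1, the lowest at -0.246, and 8 matched their own number best. With a replicate block 3007 genes changed at 72 h of 9cRA, 26 differed between compounds at 24 h, 29 and 30 with time in RA and 9cRA, and 6 in the interaction, and the list calls kept their side in 92 of 92. For time in RA it ended the call of no gene named and of no list.

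Leaving out each replicate gave 1180 to 6885 genes at 24 h and 5564 to 10390 at 72 h of RA, 184 to 2508 and 40 to 2455 in 9cRA, 0 to 1 and 265 to 8754 between compounds at 24 h and 72 h, 0 to 733 and 1 to 19 with time in RA and 9cRA, 0 to 4 in the interaction, and 79 to 114 list calls. All the highest counts came without RA 72 h replicate 3. With an estimated correlation 0 of 92 list calls held.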

Other observations

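Several groups of genes were not called as lists against control in any group. Retinoic acid synthesis genes had medians of 0.19 and 0.21 after 24 h and 72 h of RA and -0.04 and -0.22 after 24 h and 72 h of 9cRA (adjusted p = 0.267, 0.452, 0.946 and 0.152), although 3, 4, 1 and 1 of 14 members rose and 2, 2, 0 and 0 fell. Of the retinoid receptors, 8 genes with medians between -0.16 and 0.01, none of the 4 tests passed (adjusted p = 0.79, 0.779, 0.479 and 0.737). Skeletal muscle genes had medians of 0.02 to 0.10 over 46 members (adjusted p = 0.36, 0.567, 0.237 and 0.728). Under median centring these were 0.67, 0.93, 0.32 and 0.58, with all genes at 0.112, 0.28, 0.016 and 0.153, and called in each group (adjusted p = 1.2e-08, 2.15e-05, 1.37e-09 and 1.84e-05), and with Agilent's log ratio 3 of the 4 turned to -0.06 to -0.01. Vitellogenin and oestrogen response genes had medians of 0.03 to 0.09 over 8 members (adjusted p = 0.149, 0.452, 0.17 and 0.352), and under median centring -0.08 and -0.22 after 24 h and 72 h of RA (0.397 and 0.0625) and -0.11 after 72 h of 9cRA (0.0227). Clock genes changed singly and not as a list, with 8 higher and 3 lower of 33 after 24 h of RA, 10 and 9 after 72 h of RA, 8 and 1 after 24 h of 9cRA and 1 and 1 after 72 h of 9cRA (adjusted p = 0.369, 0.889, 0.127 and 0.745). After self-to-self subtraction the clock list was called at 24 h of 9cRA (0.00162) and the synthesis list at 72 h of 9cRA (0.0181, and 0.0246 with a replicate block).

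The lists of digestive organs moved together from replicate to replicate within the groups, and so did lists of other tissues. Over 12 replicates, deviations from the group means of the pancreas and liver medians correlated at r = 0.826 (permutation p = 0.0247 adjusted over 4 relations; rho = 0.741, p = 0.0424), and those of pancreas and intestine at r = 0.901 (permutation p = 0.0205 adjusted; rho = 0.874). Liver and intestine correlated at r = 0.936 (permutation p = 0.00309 adjusted; rho = 0.909), where the unadjusted 0.000772 is the smallest value that 1296 permutations can give. Pancreas and neuronal and glial medians correlated inversely, at r = -0.882 (permutation p = 0.0205 adjusted; rho = -0.881). Heart muscle correlated at r = 0.862 with pancreas and 0.934 with liver, lens crystallins at 0.784 and 0.945, fin and epidermal structural genes at 0.699 and 0.896, and xenobiotic metabolism at 0.897 and 0.859, without a test. Without the 2 farthest replicates r of the 4 tested relations was 0.725, 0.811, 0.907 and -0.769. All relations were chosen after their values were seen.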
